A study of Homo sapiens with 14 samples.

How the data were processed

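Gene expression was measured on 14 Agilent SurePrint G3 human expression arrays, each hybridised with Cy3-labelled RNA from H9 cells, a human embryonic stem cell line. Per the labels, the arrays form 7 groups of 2 replicates. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The groups lie on 2 slides. Slide 1 held the EGFP-siRNA, LIN28A-siRNA and SET7/9-siRNA arrays, and slide 2 held the TUT4-siRNA arrays and the 3 groups that received LIN28A siRNA together with an empty vector, LIN28A or LIN28A-K135R. Each group lay on a single slide, so a term for slide adds nothing to a comparison of groups within a slide, and slide and group cannot be told apart in a comparison across slides.

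The authors deposited 1 scanner file per array and a table of processed values. Per the file headers, the scanner files were written by Agilent Feature Extraction 10.10.1.1, and their processed signal is a spot intensity from which background was subtracted and a spatial trend removed within the array, with no normalization between arrays. The median spot brightness and the median local background in the same deposited files are intensities without any correction. The other deposited columns used were flags, set to 0 or 1 by the scanner software per the file headers, for spots well above background, saturated spots and outlier spots. The deposited table of processed values is on a log2 scale. Its scale was found from the values: each column followed the log2 of the background-subtracted median brightness of its own array, and the sorted columns nearly coincided, as after quantile normalization. The submitters' processing notes name limma without its role or version, and the steps behind that table are not given in the sources used here. Mean spot signals were not in the columns of the scanner files, so median signals took their place in the normexp alternative. No control spot entered a test, and 0 spots were saturated.

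Probes were named through their accessions, matched without versions to RefSeq gene symbols of assembly GRCh38.p14. Of 50599 distinct probes on 58717 spots, 29019 had 1 symbol and 21580 had none here, 58 of them because the array annotations named them differently. The accession differed between the annotations of the slides for 7364 spots. The named probes covered 20986 symbols. The array design was annotated on another assembly (hg19), so no coordinates are given. Spots of 1 probe were averaged.

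The log2 of the processed signal was taken and each array's 75th percentile subtracted. Spots with an outlier flag were left out of a probe's average. Named probes with every spot flagged on any array were left out (97). A probe was kept if it was well above background on both arrays of at least 1 group (23616), and each gene was represented by its kept probe with the highest mean over all arrays. This left 17453 genes, 4704 of which had over 1 kept probe. All arrays entered a single limma fit (limma 3.58.1, lmFit and eBayes, in R 4.3.3) with 7 group means and no covariate. The fit had 7 residual degrees of freedom, with 2.42 prior degrees of freedom and a prior variance of 0.0175. Adjusted p-values are limma's moderated p-values after Benjamini-Hochberg adjustment over all genes of a comparison, with a threshold of 0.05, and errors given with ± on a log2 change are standard errors of this fit. Every group has n = 2 arrays. Levels are log2 values relative to the array's 75th percentile. Tables were handled with the data.table package (version 1.17.8), and statmod 1.5.0 was installed. In the alternative with a replicate block, the replicate number entered the design as a fixed term. The number of arrays limits the precision of every value.

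Where a gene was not well above background on either array of a group, its fold change is a lower bound, written "at least". The bound is the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal.

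Comparisons were fixed before the data were examined: LIN28A-siRNA, SET7/9-siRNA and TUT4-siRNA against EGFP-siRNA; LIN28A and LIN28A-K135R against the empty vector; and 3 direct comparisons, LIN28A-K135R against LIN28A, SET7/9-siRNA against LIN28A-siRNA, and the vector group against LIN28A-siRNA. The rule for named genes was also fixed then. It takes, per comparison, the targeted genes, the 8 largest rises and 8 largest falls among genes that passed the test, changed the same way in all 4 pairs of arrays and were well above background on both arrays of the higher group, and up to 3 members of each gene list with the lowest p. The text prints part of them. All named genes that passed the test changed the same way in 4 of 4 pairs of arrays, so this is not repeated. XIST, Y-linked genes and probes without a gene symbol were left out of the naming, and no level of either is given.

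The 22 gene lists, fixed before the data were examined, were pluripotency, let-7 targets, microRNA biogenesis, neural and neural crest, mesoderm and mesendoderm, endoderm, trophoblast, germ cell, fibroblast, interferon response, p53 targets, unfolded protein and amino acid stress, heat shock, cell cycle, replication-dependent histones, ribosomal proteins, oxidative phosphorylation, glycolysis, splicing regulators, HOX genes, cholesterol synthesis and TGF-beta family signalling. Some genes stand in several lists, and the glycolysis list also holds hypoxia genes such as CA9. LIN28A, SETD7 and TUT4 were left out of all lists. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera with an estimated correlation, which allows for members that vary together, and fry, which does not compare the list with other genes, were alternatives.

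Correlations between comparisons that share the EGFP-siRNA or vector arrays were set beside 100 simulations of unchanged groups against shared controls, with the spread pooled over all arrays and, added after the data were seen, with the spread of the replicates of the groups compared. The fit was tested on simulated arrays for the comparison of LIN28A with vector over 17453 genes, with each gene's spread pooled over all arrays. Replicates in fact differed less in these groups (median absolute log2 difference 0.068 with LIN28A and 0.078 with vector) than on slide 1 (0.173 to 0.235). The recovery rates hold for the pooled spread only. Of genes changed by 0.5 on the log2 scale, 15 of 74 (20.3%) were recovered, of those changed by 1, 41 of 57 (71.9%), and of those changed by 2, 67 of 69 (97.1%), with 6 false calls and 0 calls among unchanged arrays. For the same comparison, a list of 40 genes shifted by 0.5 was called by camera and 0 of the flat lists were called. Genes were simulated as independent of each other, so this says nothing about false calls for lists whose members vary together.

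The alternatives were quantile normalization, normexp with an offset of 50 on the median signals followed by quantile normalization, centring on probes above background on all arrays, no filter on dim probes, only probes above background on all arrays, the mean of a gene's probes, eBayes with trend and robust, the 4 compared arrays or the arrays of the slide alone, the deposited log2 values, the replicate number as a block, and leaving out each array in turn. For TUT4-siRNA, the vector group as control and a bridge through the LIN28A-siRNA groups were added. After the data were seen, 4 alternatives were added: the vector group against TUT4-siRNA, TUT4-siRNA as control for each of the LIN28A groups, and a correlation without genes below background in the LIN28A-siRNA and SET7/9-siRNA arrays.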

Results

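To follow how the transcriptome of human embryonic stem cells responds to loss of the RNA-binding protein LIN28A, of the lysine methyltransferase SET7/9 (gene SETD7) and of the terminal uridylyltransferase TUT4, RNA from transfected H9 cells was profiled on 14 one-colour expression arrays. H9 is an established line of human embryonic stem cells. The cells had been grown on mouse fibroblast feeders, replated as single cells without feeders on matrigel and transfected with siRNAs. A control siRNA against EGFP and siRNAs against LIN28A, SET7/9 and TUT4 formed 4 groups. In the 3 other groups, LIN28A siRNA was combined with an empty vector, with LIN28A carrying silent mutations (LIN28A-siR) or with the same construct carrying the K135R substitution (LIN28A-K135R-siR). Each group had 2 arrays, and 17453 genes were tested. The 75th percentile of the signal lay between 497 and 581 on the EGFP-siRNA arrays, between 274 and 292 on the LIN28A-siRNA arrays and between 237 and 271 on the SET7/9-siRNA arrays, all on slide 1. On slide 2 it lay between 725 and 835. The share of spots well above background ran from 56.9% on a SET7/9-siRNA array to 70.7% on a TUT4-siRNA array.

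Replicate arrays correlated across genes at r = 0.990 to 0.996, where genes are not independent replicates. The LIN28A-siRNA and SET7/9-siRNA arrays were as close to each other (r = 0.987 to 0.991) as the groups of slide 2 were among themselves (r = 0.988 to 0.994), and both were far from EGFP-siRNA (r = 0.935 to 0.950 for LIN28A-siRNA). The LIN28A-siRNA arrays of slide 1 and the vector arrays of slide 2, which received the same siRNA, were farther apart (r = 0.906 to 0.911) than either was from EGFP-siRNA.

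**Figure D1:**
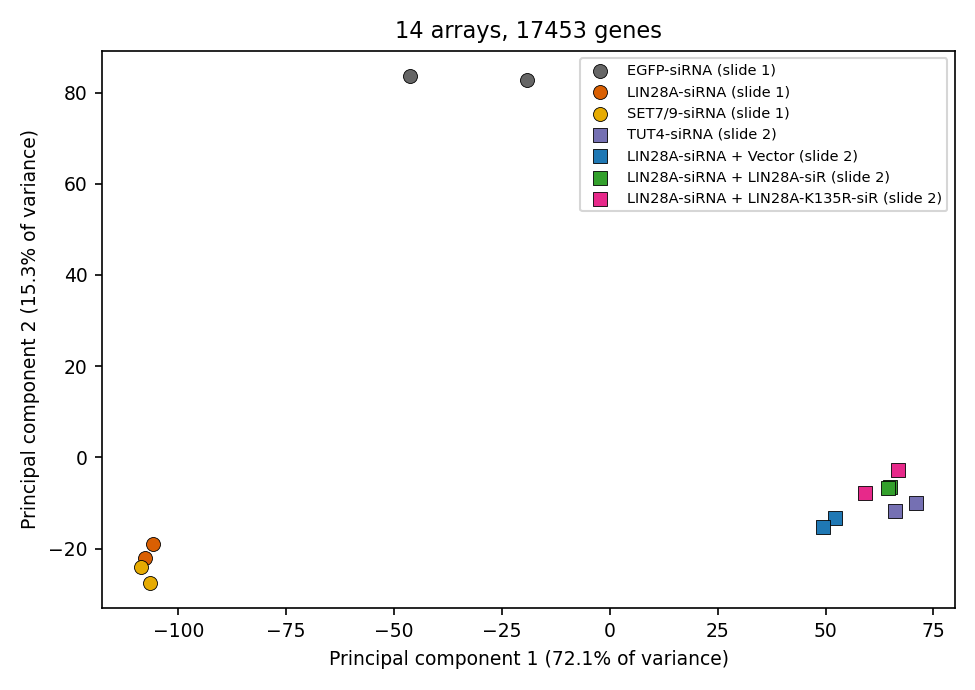
Principal components 1 (72.1% of the variance) and 2 (15.3%) of the log2 values of 17453 genes, with a point per array, circles for slide 1 and squares for slide 2. The 14 arrays form 3 clusters: EGFP-siRNA, LIN28A-siRNA with SET7/9-siRNA, and all groups of slide 2. On component 2 the EGFP-siRNA arrays (82.8 and 83.6) stand apart from all other arrays, which have negative values.

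The targeted genes were examined first. LIN28A stood at a log2 level of 3.82 ± 0.08 (SD, n = 2) in EGFP-siRNA and 3.44 ± 0.29 in LIN28A-siRNA, a 1.30-fold fall (log2 change −0.38 ± 0.13, adjusted p = 0.0262). It was 1.27-fold lower in the SET7/9-siRNA arrays as well (−0.34, adjusted p = 0.0412), and its level differed by 0.04 ± 0.13 between these groups (adjusted p = 0.938), so LIN28A does not separate them. The call in the SET7/9-siRNA arrays was lost without either array of either group (changes of −0.40 to −0.28, adjusted p = 0.0569 to 0.166). Without EGFP-siRNA replicate 2 the change in LIN28A-siRNA was −0.32 (adjusted p = 0.103), and without LIN28A-siRNA replicate 2 it was −0.17 (adjusted p = 0.154). In a fit of the arrays of slide 1 alone it did not pass the test (adjusted p = 0.156). SETD7 was not lower in the arrays labelled SET7/9-siRNA than in EGFP-siRNA: its level was −2.90 ± 0.52 there and −3.34 ± 0.16 in EGFP-siRNA (change 0.44 ± 0.24, adjusted p = 0.138). Without SET7/9-siRNA replicate 2, SETD7 was higher by 0.80 (adjusted p = 0.0139). In the LIN28A-siRNA arrays SETD7 rose by 1.77 ± 0.24 (adjusted p = 2.24e-04). Set directly against these, the SET7/9-siRNA arrays had SETD7 at −1.33 ± 0.24 (adjusted p = 0.0825), which passed the test with normexp (−0.81, adjusted p = 0.0456), with quantile normalization (−1.43, adjusted p = 0.0498) and without SET7/9-siRNA replicate 1 (−1.69, adjusted p = 0.0142). TUT4 was not lower in the arrays labelled TUT4-siRNA either, where it stood 1.82-fold above EGFP-siRNA (0.87 ± 0.11, adjusted p = 1.26e-04) and level with the vector arrays of its own slide (0.045 ± 0.11, adjusted p = 0.899).

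In cells that received LIN28A siRNA on slide 2, LIN28A rose 1.71-fold with LIN28A-siR (0.78 ± 0.13, adjusted p = 0.0119) and 1.59-fold with LIN28A-K135R-siR (0.67 ± 0.13, adjusted p = 0.0355), and the constructs differed by −0.11 ± 0.13 (adjusted p = 1). Leaving out either array of a compared group ended both calls, at changes of 0.75 to 0.80 (adjusted p = 0.0766 to 0.0926) and of 0.64 to 0.70 (adjusted p = 0.11 to 0.211). LIN28A, SETD7 and TUT4 have 1 probe each, and whether the LIN28A probe lies within the cloned sequence is not known here.

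**Figure D2:**
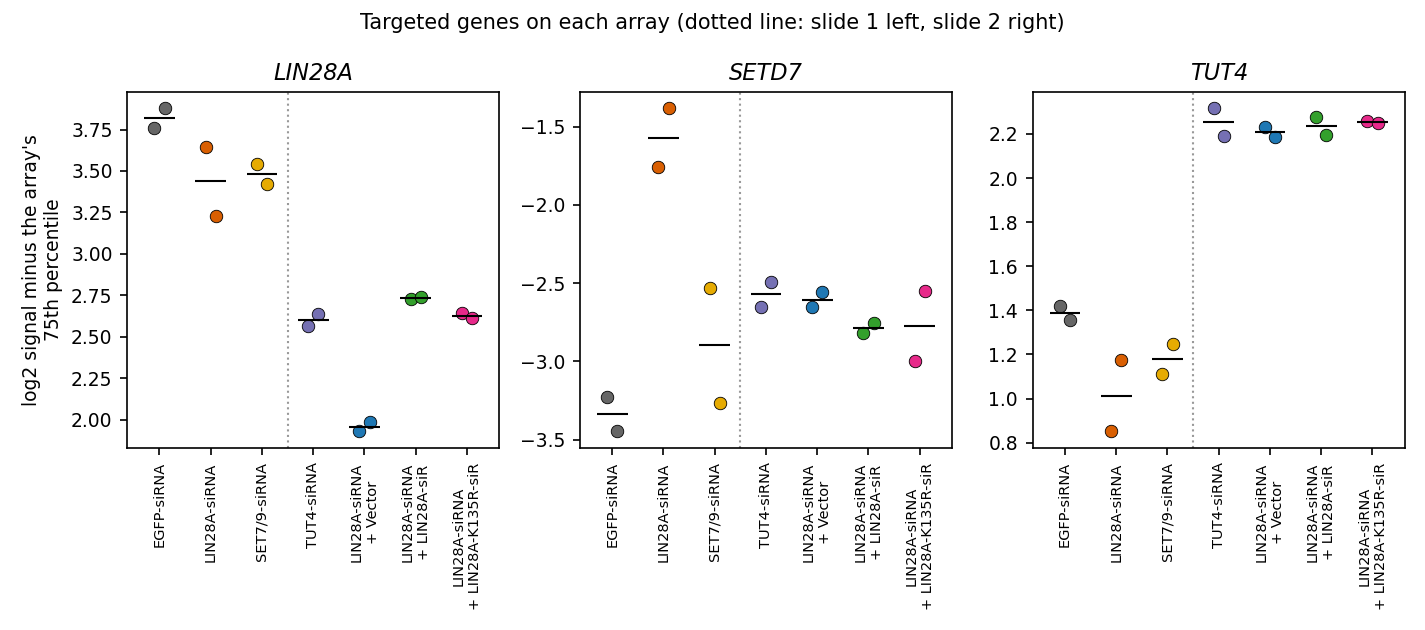
Log2 signal relative to the array's 75th percentile for the targeted genes, with a point per array, a bar at the mean of each group of 2 and slide 1 left of the dotted line. LIN28A lies between 3.44 and 3.82 on average in the groups of slide 1 and between 1.96 and 2.73 in those of slide 2.

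The LIN28A-siRNA arrays were compared with EGFP-siRNA to ask which transcripts change with depletion of LIN28A. GDF15, a secreted cytokine of the p53 and stress responses, was 39.9-fold higher (5.32 ± 0.18). FOSB, an immediate early transcription factor, was 115-fold lower (−6.85 ± 0.18), and the glycolytic enzymes ALDOC and GAPDH were 13.3-fold and 5.66-fold lower. The test called 9871 genes, 5244 higher and 4627 lower, of which 2118 and 1278 changed at least 2-fold.

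The largest rises included PABPN1L (61.6-fold), WFDC21P (41.2-fold), LCP1, which encodes an actin-bundling protein (40.3-fold), LY96, a partner of Toll-like receptor signalling (at least 23.3-fold), and the ligand WNT7A (at least 17.7-fold). The largest falls included the cancer-testis antigens CTAG1A (at least 452-fold) and CTAG2 (80.8-fold), MAGEH1 of the MAGE family (at least 22.2-fold), DDX43 (at least 17.4-fold) and CRYZ (at least 15.9-fold), and the immediate early factors EGR4 (84.6-fold) and EGR3 (at least 19.4-fold). The vector arrays of slide 2 also received LIN28A siRNA. There CTAG1A (5.9 and 5.9), MAGEH1 (1.4 and 1.5), DDX43 (0.8 and 0.8) and CRYZ (0.8 and 0.7) stood above both EGFP-siRNA arrays, across slides, so these falls did not recur with the same siRNA. GDF15 (4.9 and 5.1) was above EGFP-siRNA (2.3 and 2.2) there as well. It was also above EGFP-siRNA on the TUT4-siRNA arrays (4.3 and 4.7), which received no LIN28A siRNA, and with both LIN28A constructs. Its level on slide 2 therefore does not tie the rise to LIN28A siRNA. FOSB, EGR3 and EGR4 were also lower than in EGFP-siRNA on the TUT4-siRNA arrays, across slides. EGR4 was lower as well on the arrays labelled with siRNA against SETD7. Neither group received LIN28A siRNA, so these falls are not tied to it either. All these comparisons share the EGFP-siRNA arrays, and a high level there was not told apart from an effect of LIN28A siRNA.

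Of 36 p53 targets, 30 rose and 1 fell (31 and 1 adjusted over the list alone), with a median change of 1.37 (adjusted p = 5.41e-10, adjusted p = 0.275 with an estimated correlation). They included the death receptor TNFRSF10A (5.14-fold). Of 45 genes of the unfolded protein and amino acid stress list, 24 rose and 6 fell (the same adjusted over the list alone; adjusted p = 0.00174, adjusted p = 0.321 with an estimated correlation), led by TRIB3 (5.81-fold) and NUPR1 (2.01 on the log2 scale). Of 27 interferon response genes 14 rose and 4 fell, likewise adjusted over the list alone, among them IFIT1 (4.14-fold) and IFIT3 (at least 3.96-fold). That list's call (adjusted p = 0.017) was lost with an estimated correlation (adjusted p = 0.331) and without EGFP-siRNA replicate 1 (adjusted p = 0.0737).

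Of 41 pluripotency genes, 9 rose and 27 fell (9 and 29 adjusted over the list alone), with a median of −0.74 (adjusted p = 1.51e-04, adjusted p = 0.331 with an estimated correlation). GDF3 fell at least 23.1-fold and PRDM14, a transcriptional regulator of the pluripotent state, 7.11-fold, whereas the Nodal antagonist LEFTY2 rose 11.1-fold. Of 19 trophoblast markers 13 rose and 0 fell, also adjusted over the list alone (adjusted p = 1e-04, adjusted p = 0.0553 with an estimated correlation), including MUC15 (at least 5.67-fold) and CGA, the alpha subunit of the glycoprotein hormones (at least 7.05-fold). Of 17 endoderm markers 11 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.008, adjusted p = 0.321 with an estimated correlation), with alpha-fetoprotein AFP 8.63-fold higher. Of 28 fibroblast genes 15 rose and 2 fell, also over the list alone (adjusted p = 9.75e-04, adjusted p = 0.321 with an estimated correlation), among them TIMP3 (9.24-fold). Of 33 neural and neural crest genes 19 rose and 6 fell, also over the list alone, a call (adjusted p = 0.0353) that ended with an estimated correlation (adjusted p = 0.341), without EGFP-siRNA replicate 2 (adjusted p = 0.162) and without LIN28A-siRNA replicate 1 (adjusted p = 0.0511). MAP2 of that list rose by 1.80 and HES5 fell by 1.45. The mesoderm (adjusted p = 0.174) and germ cell lists (adjusted p = 0.174) were not called, although TWIST1, a mesenchymal transcription factor, rose 17.8-fold and LHX1 9.95-fold.

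Among lowered lists, 25 of 27 glycolysis genes fell and 0 rose, also adjusted over the list alone, with a median of −1.26 (adjusted p = 7.98e-11, adjusted p = 0.321 with an estimated correlation), including the pyruvate dehydrogenase kinase PDK1 (7.35-fold). Of 59 replication-dependent histone genes 45 fell and 1 rose (46 and 1 adjusted over the list alone; adjusted p = 3.62e-10, adjusted p = 0.331 with an estimated correlation), among them H1-2, which fell by 1.88. Of 54 cell cycle genes 38 fell and 4 rose, also over the list alone (adjusted p = 2.28e-07, adjusted p = 0.321 with an estimated correlation), including the helicase subunit MCM2 (2.55-fold) and E2F1 (2.24-fold). Of 43 splicing regulators 31 fell and 3 rose (32 and 3 adjusted over the list alone), with SRSF2 2.44-fold lower (adjusted p = 1.98e-07). This call also held with an estimated correlation (adjusted p = 0.0448). Of 74 oxidative phosphorylation genes 37 fell and 1 rose (36 and 0 adjusted over the list alone; adjusted p = 1.34e-05, adjusted p = 0.467 with an estimated correlation). Of 25 cholesterol synthesis genes 14 fell and 0 rose (15 and 1 adjusted over the list alone; adjusted p = 4.1e-04, adjusted p = 0.361 with an estimated correlation). They included LSS, lanosterol synthase (2.29-fold).

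Of 22 heat shock genes 11 fell and 2 rose, also over the list alone (adjusted p = 0.0165, adjusted p = 0.356 with an estimated correlation), with HSPA8 lower by 0.93 on the log2 scale. The heat shock call ended with quantile normalization (adjusted p = 0.185), with normexp (adjusted p = 0.177) and without LIN28A-siRNA replicate 2 (adjusted p = 0.0875). Of 25 microRNA biogenesis genes 12 fell and 3 rose, also over the list alone (adjusted p = 0.0132, adjusted p = 0.154 with an estimated correlation), a call that ended with normexp (adjusted p = 0.0843). The let-7 targets, a class of mRNAs linked to LIN28A through the let-7 microRNAs, went both ways, with 21 of 65 higher and 13 lower, also over the list alone (adjusted p = 0.529): MYCN fell 3.85-fold and CPEB2 rose by 2.61. HOX genes (5 higher and 12 lower of 27, also over the list alone, adjusted p = 0.0583) and ribosomal proteins (2 higher and 7 lower of 78, 0 and 3 adjusted over the list alone, adjusted p = 0.174) were not called. HOX genes were called lower after quantile normalization (adjusted p = 0.0011), with normexp (adjusted p = 0.00369), without EGFP-siRNA replicate 2 (adjusted p = 0.0108) and without LIN28A-siRNA replicate 2 (adjusted p = 0.0485), and ribosomal proteins were called lower without LIN28A-siRNA replicate 1 (adjusted p = 2.96e-05). In TGF-beta family signalling 12 of 39 genes rose and 14 fell (13 and 14 adjusted over the list alone; adjusted p = 0.89). The median was −0.05 and the mean 0.40, and TGFB2 rose by 2.68.

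Of the 80 named genes called in this comparison, 78 were called in every fit that left out 1 array. Fits of only the 4 arrays compared and of only slide 1 called 5800 and 6437 genes. On slide 2, the vector arrays, which also received LIN28A siRNA, differed from the TUT4-siRNA arrays in 442 genes, a comparison chosen after the data were seen.

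**Figure D3:**
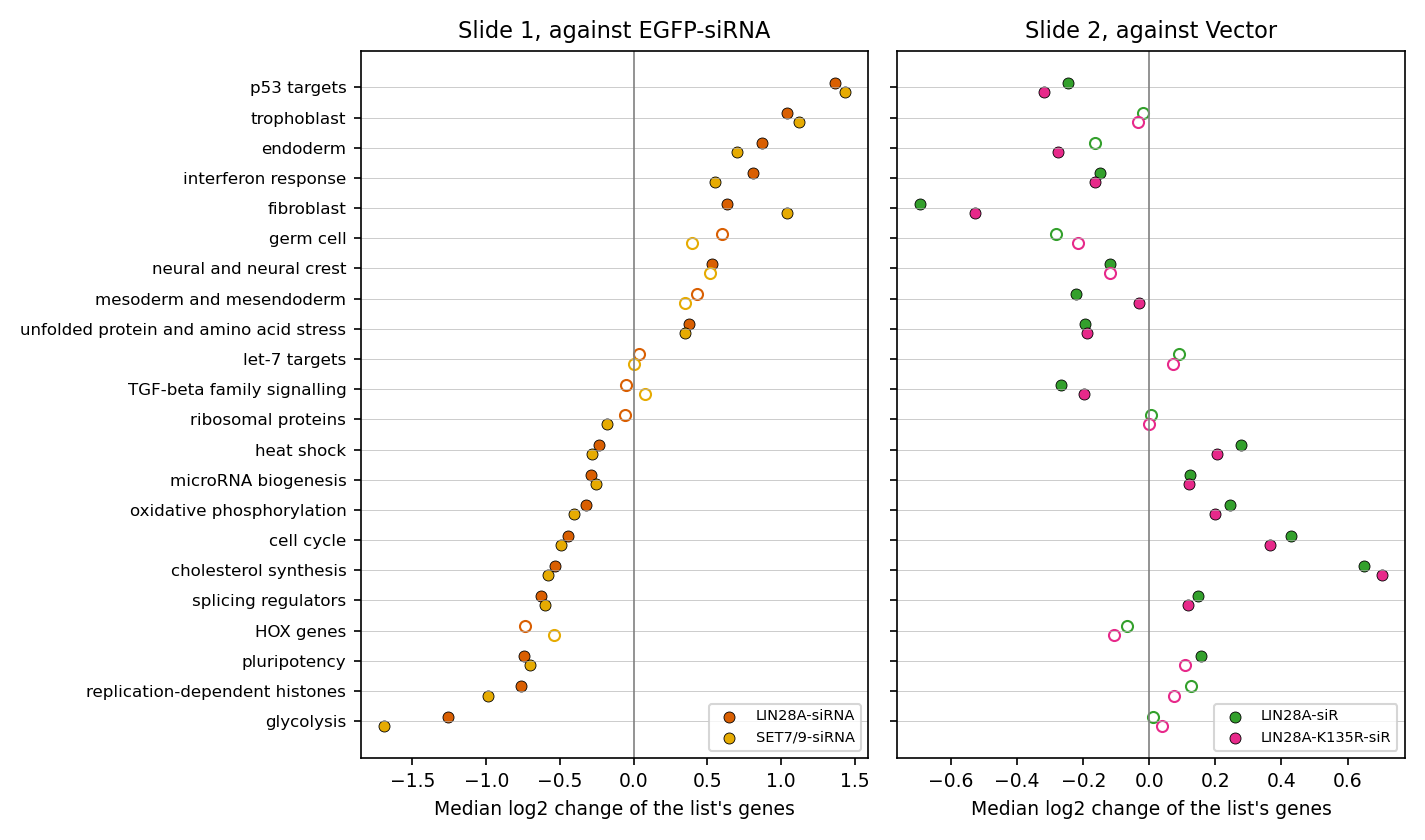
Median log2 change of the members of each of 22 gene lists, for the comparisons with EGFP-siRNA on slide 1 (left) and with vector on slide 2 (right), with filled points where camera with a preset correlation gave an adjusted p under 0.05 and hollow points elsewhere. On slide 1 the LIN28A-siRNA and SET7/9-siRNA points lie close together, from 1.37 and 1.44 for p53 targets to −1.26 and −1.69 for glycolysis.

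The arrays labelled SET7/9-siRNA, in which SETD7 itself was not lower than in EGFP-siRNA, showed nearly the same differences from EGFP-siRNA. GDF15 was 35.5-fold higher (5.15 ± 0.18), the kinase PLK2 11.8-fold and LEFTY2 12.8-fold. PRDM14 was 7.55-fold lower, PDK1 8.1-fold and EGR4 175-fold, and CTAG1A at least 417-fold. The largest rises included the peptide hormone UCN2 (55.8-fold), THSD7A (46.2-fold), LY96 (at least 26.8-fold) and the matrix metalloproteinase MMP10 (at least 13.6-fold). In all, 10117 genes differed, 5217 higher and 4900 lower, and 2204 and 1372 changed at least 2-fold. Fits of only these 4 arrays and of only slide 1 called 6069 and 6727.

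In these arrays 30 of 36 p53 targets rose and 1 fell (31 and 1 adjusted over the list alone; adjusted p = 6.58e-11, adjusted p = 0.233 with an estimated correlation). Trophoblast markers rose in 12 of 19 cases and fell in 0, also over the list alone (adjusted p = 8.12e-05, adjusted p = 0.0522 with an estimated correlation). Fibroblast genes rose in 17 of 28 cases and fell in 3, also over the list alone (adjusted p = 3.33e-04, adjusted p = 0.36 with an estimated correlation), with TIMP3 11.9-fold higher. Of 59 histone genes 54 fell and 1 rose (55 and 1 adjusted over the list alone; adjusted p = 2.48e-12, adjusted p = 0.383 with an estimated correlation). Of 27 glycolysis genes 25 fell and 0 rose, also over the list alone (adjusted p = 5.4e-11, adjusted p = 0.36 with an estimated correlation). Of 54 cell cycle genes 39 fell and 3 rose, also over the list alone (adjusted p = 7.4e-08, adjusted p = 0.36 with an estimated correlation), and 27 of 41 pluripotency genes fell and 9 rose (29 and 9 adjusted over the list alone; adjusted p = 5.9e-04, adjusted p = 0.383 with an estimated correlation). Splicing regulators, with 31 of 43 lower and 3 higher, also over the list alone, were called with the preset (adjusted p = 2.82e-07) and with an estimated correlation (adjusted p = 0.0496). In each of these comparisons camera called 16 of 22 lists, and splicing regulators were the 1 list that held with an estimated correlation. Ribosomal protein genes fell in 21 of 78 cases and rose in 0 (11 and 0 adjusted over the list alone; adjusted p = 0.00378, adjusted p = 0.683 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.37), with normexp (adjusted p = 0.311) and without SET7/9-siRNA replicate 2 (adjusted p = 0.0874).

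Across genes, the changes against EGFP-siRNA in the LIN28A-siRNA and SET7/9-labelled arrays correlated at r = 0.952. Unchanged groups simulated against 2 shared controls with the spread pooled over all arrays gave 0.501, and 0.536 with the spread of these groups' own replicates. The covariance was 0.931 against 0.0249 and 0.0461, and the sign was the same for 90.7% of genes (66.7% and 69.3% simulated). Genes called higher in both numbered 4511 and lower in both 4097, where independent lists of these sizes would share 1568 and 1299, and 10 genes were called in opposite directions. The 2 control arrays were not split between the comparisons, so part of the excess may come from the shared controls.

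**Figure D4:**
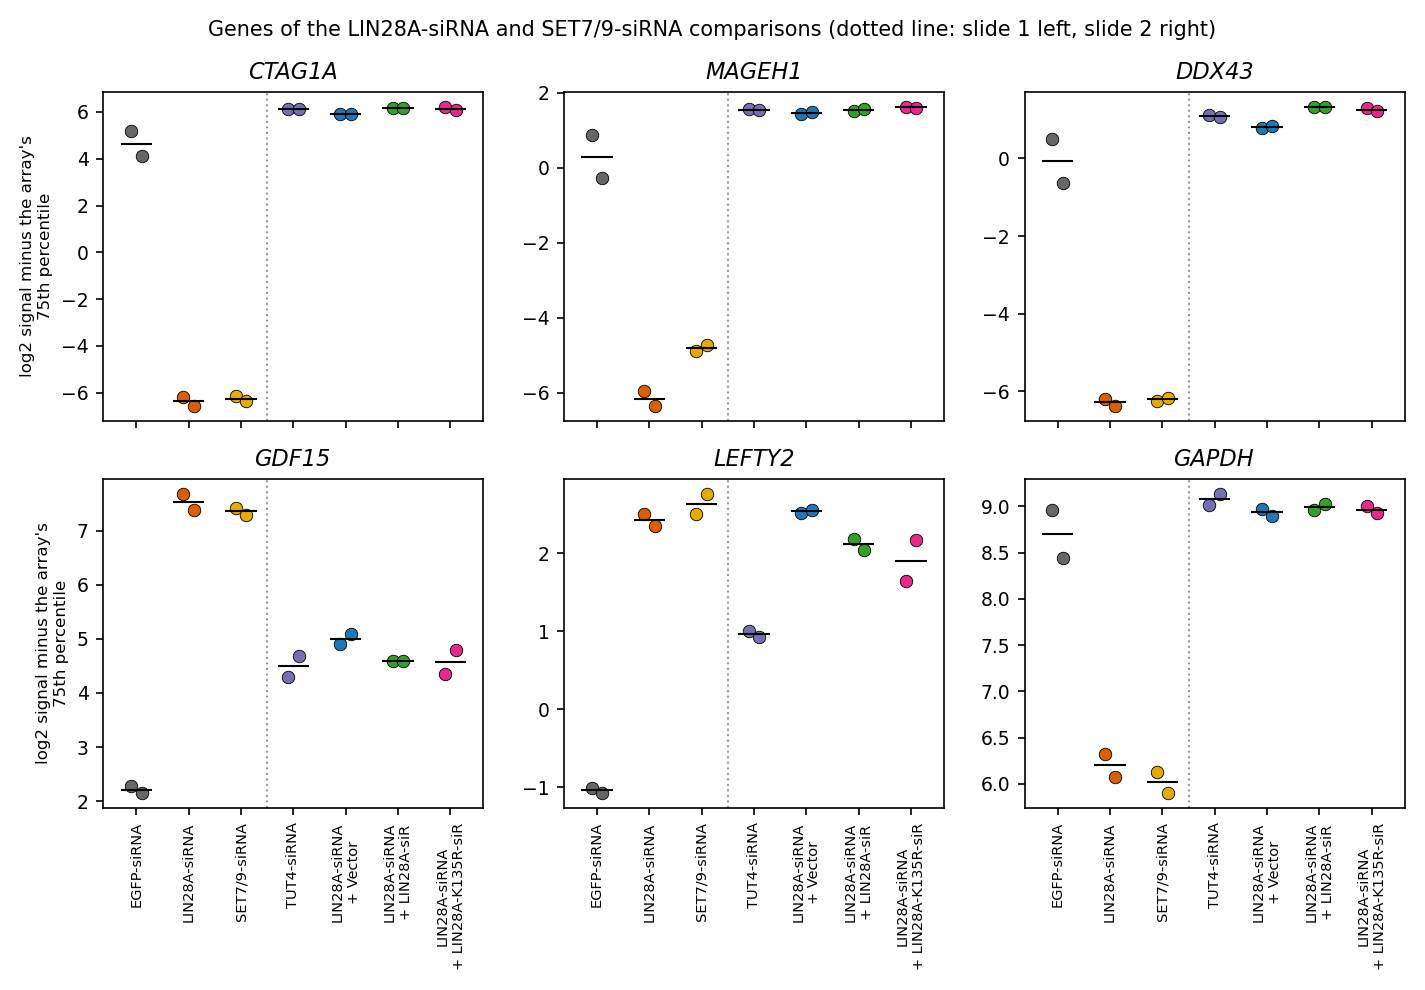
Log2 signal relative to the array's 75th percentile for CTAG1A, MAGEH1, DDX43, GDF15, LEFTY2 and GAPDH, with a point per array, a bar at the mean of each group of 2 and slide 1 left of the dotted line. CTAG1A lies between −6.57 and −6.13 on the LIN28A-siRNA and SET7/9-siRNA arrays and at 4.10 and 5.19 on the EGFP-siRNA arrays. On the vector arrays, which also received LIN28A siRNA, it lies at 5.89 and 5.91.

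Set against each other directly, the SET7/9-labelled and LIN28A-siRNA arrays differed in 28 genes, 8 higher and 20 lower in the former. SIM2 was at least 6.69-fold higher, FBLN5, an extracellular matrix protein, 2.47-fold (1.30 ± 0.19) and TRAM2 1.71-fold. The mesoderm factor MESP1 was 2.61-fold lower (−1.38 ± 0.19, adjusted p = 0.0308), the Wnt receptor FZD10 lower by 0.90 on the log2 scale and SOX17 at least 1.18-fold lower. The count depended on single arrays and settings: it was 3 for the arrays of slide 1 alone, 2 for the 4 arrays alone, 10 without a filter on dim probes, 0 with only probes above background on all arrays (1969 genes had an unadjusted p under 0.05 with all probes), 75 with quantile normalization and 63 with the deposited values. Of the calls, 71.0% were higher with normexp and 42.9% with the deposited values, against 28.6%. The count was 40 without LIN28A-siRNA replicate 1, 150 without replicate 2, 200 without SET7/9-siRNA replicate 1 and 128 without replicate 2, and 4 of 14 named genes were called in each of these fits. With the preset correlation, histones (median −0.22, adjusted p = 1.07e-06), ribosomal proteins (−0.13, adjusted p = 2.96e-05), glycolysis (−0.18, adjusted p = 0.014), p53 targets (0.08, adjusted p = 0.0206) and fibroblast genes (0.17, adjusted p = 0.0282) were called, although 1 glycolysis gene and 0 genes of the other lists passed the test singly (1 fibroblast and 1 p53 gene adjusted over the list alone). Each had an adjusted p = 0.997 with an estimated correlation. Each call was lost when an array was left out: without LIN28A-siRNA replicate 1 for histones (adjusted p = 0.878), fibroblast genes and glycolysis (adjusted p = 0.349 for both), without SET7/9-siRNA replicate 1 for glycolysis (adjusted p = 0.239), without SET7/9-siRNA replicate 2 for histones (adjusted p = 0.207), ribosomal proteins and p53 targets (adjusted p = 0.47 for both) and fibroblast genes (adjusted p = 0.589), and without LIN28A-siRNA replicate 2 for p53 targets (adjusted p = 0.299). Ribosomal proteins turned direction without LIN28A-siRNA replicate 1 (adjusted p = 0.13).

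The TUT4-siRNA arrays, in which TUT4 itself was not lower, lay on another slide than EGFP-siRNA, so slide and group cannot be told apart in this comparison. Among the falls, the immediate early gene EGR1 was 151-fold lower (−7.24 ± 0.14), EGR4 at least 606-fold, EGR3 at least 69.6-fold and FOSB 99.7-fold. PAX6, a neural transcription factor, was 97.5-fold lower, HSPA1A, an inducible heat shock chaperone, 8.9-fold and MYC 7.33-fold. Among rises were the testis-type lactate dehydrogenase LDHC (26.1-fold), ZNF680 (at least 13.5-fold) and TRIM60 (at least 9.73-fold). The test called 11181 genes, 5362 higher and 5819 lower. Of these, 9511 (85.1%) were called the same way when the vector arrays of slide 2 were set against EGFP-siRNA.

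Of 27 glycolysis genes 23 rose and 0 fell, also adjusted over the list alone (median 0.95, adjusted p = 3.71e-05, adjusted p = 0.898 with an estimated correlation), including the hypoxia-induced carbonic anhydrase CA9 (7.82-fold) and hexokinase HK2 (3.03-fold). HOX genes rose in 18 of 27 cases and fell in 2 (18 and 4 adjusted over the list alone; adjusted p = 4.04e-04, adjusted p = 0.473 with an estimated correlation), with HOXA4 5.1-fold higher. Pluripotency genes fell in 32 of 41 cases and rose in 3 (32 and 4 adjusted over the list alone; adjusted p = 2.52e-05, adjusted p = 0.523 with an estimated correlation), among them HESX1 (13.4-fold) and VRTN (11.1-fold). Of 22 heat shock genes 18 fell and 1 rose, also over the list alone (adjusted p = 7.64e-05, adjusted p = 0.523 with an estimated correlation). Histones (33 lower and 4 higher of 59, also over the list alone, adjusted p = 6.49e-04, adjusted p = 0.898 with an estimated correlation) and splicing regulators (25 lower and 5 higher of 43, also over the list alone, adjusted p = 0.009, adjusted p = 0.473 with an estimated correlation) were lower, the latter led by the epithelial regulator ESRP1 (14.7-fold). Cell cycle genes (25 lower and 7 higher of 54, also over the list alone, adjusted p = 0.0335, adjusted p = 0.898 with an estimated correlation) were not called without EGFP-siRNA replicate 1 (adjusted p = 0.119).

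Against the vector arrays of the same slide, the TUT4-siRNA arrays differed in 442 genes, 63 higher and 379 lower, and 245 of the genes called against EGFP-siRNA were called the same way. Fibroblast genes fell in 14 of 28 cases (26 adjusted over the list alone) and rose in 0, with a median of −0.92 (adjusted p = 1.26e-24), and TGF-beta family genes fell in 11 of 39 (19 adjusted over the list alone) and rose in 0 (adjusted p = 6.94e-12). Both calls held with an estimated correlation (adjusted p = 0.0262 and adjusted p = 0.0374). Cholesterol synthesis genes rose in 7 of 25 cases (19 adjusted over the list alone) and fell in 0, with a median of 0.48 (adjusted p = 6.68e-17, adjusted p = 0.129 with an estimated correlation). A bridge to EGFP-siRNA added the TUT4-siRNA difference from vector to the LIN28A-siRNA difference from EGFP-siRNA. It removes the slide only if the vector had no effect and the cells were otherwise alike on both slides, which was not shown. With this bridge, 6209 genes were called. Glycolysis was then lower (adjusted p = 1.21e-11) and p53 targets and trophoblast markers higher (adjusted p = 1.66e-06 and adjusted p = 1.54e-04). HOX genes turned direction and were not called (adjusted p = 0.159). TUT4 was lower by a log2 change of −0.33 that did not pass the test (adjusted p = 0.134). These directions are also those of LIN28A-siRNA against EGFP-siRNA (TUT4 levels 1.01 and 1.39), so they say little about TUT4 siRNA.

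The vector arrays and the LIN28A-siRNA arrays, which share their siRNA and differ in slide and vector, differed in 12062 genes, 5067 higher and 6995 lower with vector, with 2188 and 3344 changed at least 2-fold. CTAG2 was 174-fold higher with vector, the matrix-crosslinking enzyme LOX 103-fold, OLIG3 at least 106-fold, ALDOC 18.3-fold and PDK1 16.7-fold. FEZF1, a forebrain transcription factor, was at least 122-fold lower, the Wnt antagonist DKK1 at least 79.1-fold and HAPLN1 49.1-fold. All 27 glycolysis genes were higher, also over the list alone (median 2.31, adjusted p = 7.1e-13, adjusted p = 0.481 with an estimated correlation), while 33 of 36 p53 targets were lower and 1 higher, also over the list alone (median −0.96, adjusted p = 4.94e-07, adjusted p = 0.481 with an estimated correlation). All 85 named genes and 7 lists called were called in every fit that left out 1 array.

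LIN28A-siR was set against empty vector in LIN28A-siRNA cells, on slide 2, to see which genes respond when LIN28A is supplied again. The isomerase IDI1 rose 2.34-fold (1.23 ± 0.12, adjusted p = 0.0012), and the growth factor FGF4 2.49-fold (1.32 ± 0.15, adjusted p = 0.00199). The collagen COL3A1 fell at least 19.1-fold (adjusted p = 7.48e-06), the receptor PDGFRB 4.4-fold (−2.14 ± 0.15) and the ligand TGFB2 4.88-fold (−2.29 ± 0.12). On slide 1, COL3A1 was not well above background with EGFP-siRNA or with LIN28A-siRNA. IDI1 stood there at 1.6 and 1.3 with LIN28A-siRNA and at 1.8 and 1.5 with EGFP-siRNA. PDGFRB and TGFB2, in contrast, were higher with LIN28A-siRNA than with EGFP-siRNA. The test called 809 genes, 384 higher and 425 lower, of which 40 and 162 changed at least 2-fold.

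Of 25 cholesterol synthesis genes 16 rose (23 adjusted over the list alone) and 0 fell, with a median of 0.65 (adjusted p = 6.16e-19, adjusted p = 0.101 with an estimated correlation), including MSMO1 (3.2-fold), MVK, mevalonate kinase (1.86-fold), and FDFT1, squalene synthase (1.73-fold). Of 54 cell cycle genes 27 rose and 0 fell (38 and 1 adjusted over the list alone; median 0.43, adjusted p = 2.02e-21, adjusted p = 0.101 with an estimated correlation), among them topoisomerase TOP2A (1.62-fold), AURKB (1.66-fold) and CCNB1 (1.63-fold). Of 28 fibroblast genes 11 fell (19 adjusted over the list alone) and 0 rose, with a median of −0.69 (adjusted p = 7.67e-18, adjusted p = 0.07 with an estimated correlation), including TIMP3 (2.58-fold). Further falls outside the list were the endothelin receptor EDNRA (at least 6.56-fold), the mesenchymal factor PRRX1 (at least 8.7-fold) and thrombomodulin THBD (8.41-fold). Of 39 TGF-beta family genes 5 fell, also over the list alone, and 0 rose (adjusted p = 6.76e-06, adjusted p = 0.101 with an estimated correlation), and of 25 mesoderm genes 5 fell (6 adjusted over the list alone) and 0 rose (adjusted p = 0.0113, adjusted p = 0.101 with an estimated correlation), including PDGFRA (2.02-fold).

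Smaller shifts with LIN28A-siR went up in oxidative phosphorylation, with 3 of 74 genes higher and 0 lower, also over the list alone (median 0.24, adjusted p = 1.04e-11, adjusted p = 0.343 with an estimated correlation). They went down in the unfolded protein list, with 9 of 45 lower (13 adjusted over the list alone; adjusted p = 5.56e-06, adjusted p = 0.108 with an estimated correlation), and in p53 targets, with 4 of 36 lower (10 adjusted over the list alone; adjusted p = 3.26e-05, adjusted p = 0.282 with an estimated correlation). TRIB3 fell by 0.71 and SESN2 by 0.61. Of 41 pluripotency genes 5 rose and 1 fell (9 and 2 adjusted over the list alone), among them L1TD1 (1.71-fold) and the methyltransferase DNMT3B (1.5-fold). That call (adjusted p = 0.0203) was lost with an estimated correlation (adjusted p = 0.485), with quantile normalization (adjusted p = 0.0784), with normexp (adjusted p = 0.0801), without LIN28A-siR replicate 1 (adjusted p = 0.0626) and without vector replicate 1 (adjusted p = 0.0674). The lists of let-7 targets (median 0.09, adjusted p = 0.167), glycolysis (adjusted p = 0.874) and trophoblast markers (adjusted p = 0.868) were not called.

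The number of genes called with LIN28A-siR moved with the arrays and settings of the fit. It was 157 without LIN28A-siR replicate 1, 211 without its replicate 2, 147 without vector replicate 1, 96 without its replicate 2, 4564 for the arrays of slide 2 alone, 3709 for the 4 arrays alone, 1545 without a filter, 1214 with trend and robust and 494 with the deposited values, where 23.5% of the calls were higher against 47.5%. Of 56 named genes called, 12 were called in every fit that left out 1 array, among them COL3A1, EDNRA, PRRX1, THBD, PDGFRB, TIMP3, TGFB2, IDI1 and FGF4, and 13 of 14 lists were. The vector arrays, where LIN28A was lowest (1.96), stood apart on slide 2. TUT4-siRNA, with no construct and no LIN28A siRNA, was called different from vector in the same direction in 10 of these 14 lists. Among them were fibroblast, TGF-beta family, cholesterol synthesis and cell cycle genes (adjusted p = 1.52e-12 for the last, adjusted p = 0.129 with an estimated correlation). Both comparisons share the vector arrays, so some agreement would arise without any effect. With the TUT4-siRNA arrays as control, a choice made after the data were seen, LIN28A-siR differed in 47 genes and LIN28A-K135R-siR in 25.

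**Figure D5:**
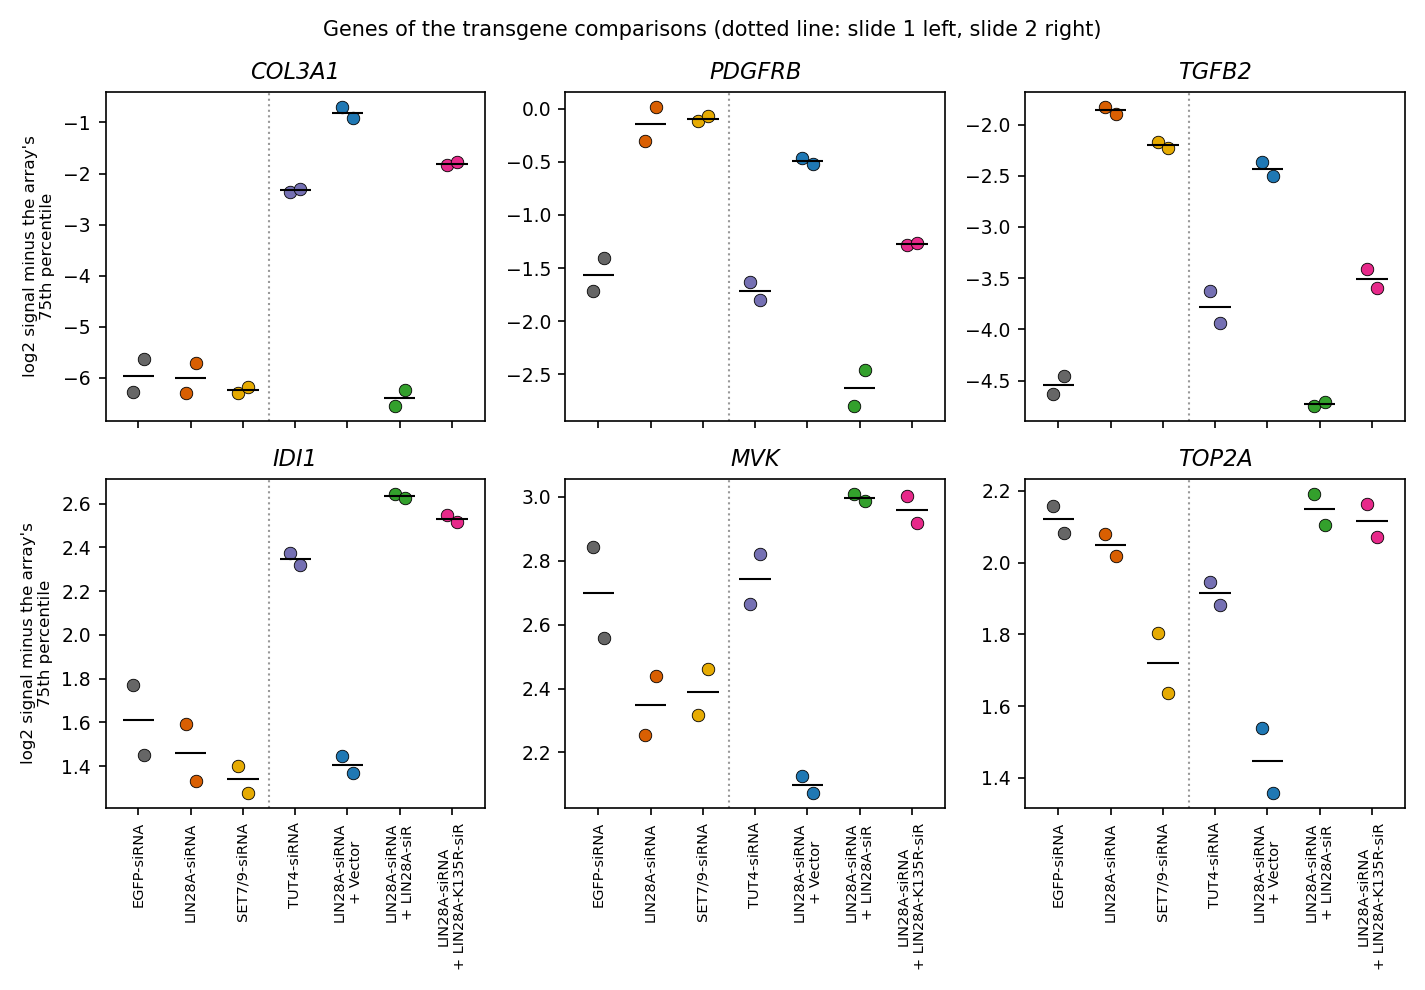
Log2 signal relative to the array's 75th percentile for COL3A1, PDGFRB, TGFB2, IDI1, MVK and TOP2A, with a point per array, a bar at the mean of each group of 2 and slide 1 left of the dotted line. Right of the line, COL3A1, PDGFRB and TGFB2 are lower with LIN28A-siR than with vector (at least 19.1-fold for COL3A1, which was not well above background with LIN28A-siR), and IDI1, MVK and TOP2A are higher (by 1.23, 0.90 and 0.70).

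LIN28A-K135R-siR was also set against vector in LIN28A-siRNA cells. IDI1 rose 2.18-fold (1.12 on the log2 scale, adjusted p = 0.00821), the synthase HMGCS1 2.28-fold (1.19 ± 0.17) and TOP2A 1.59-fold, while TGFB2 fell 2.09-fold, TIMP3 1.76-fold and PDGFRB 1.72-fold. SYT8 rose at least 11.2-fold and the inflammasome component NLRC4 at least 3.49-fold (at least 5.63-fold with LIN28A-siR). The test called 334 genes, 177 higher and 157 lower, and 34 and 31 changed at least 2-fold. Of 25 cholesterol synthesis genes 13 rose (23 adjusted over the list alone) and 0 fell (median 0.70, adjusted p = 1.45e-19, adjusted p = 0.113 with an estimated correlation), and of 54 cell cycle genes 17 rose and 0 fell (38 and 1 adjusted over the list alone; median 0.36, adjusted p = 4.71e-18, adjusted p = 0.113 with an estimated correlation). Of 28 fibroblast genes 3 fell (16 adjusted over the list alone) and 0 rose (median −0.53, adjusted p = 3.3e-13, adjusted p = 0.113 with an estimated correlation). Of 36 p53 targets 3 fell (10 adjusted over the list alone) and 0 rose (adjusted p = 5.33e-07, adjusted p = 0.235 with an estimated correlation).

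The count of 334 was 27 without LIN28A-K135R-siR replicate 1, 92 without its replicate 2, 20 without vector replicate 1 and 5 without its replicate 2, and it was 3816 for the arrays of slide 2 alone, 2 for the 4 arrays alone, 582 with trend and robust, 528 with only probes above background on all arrays, 162 without a filter and 73 with the deposited values. Of 40 named genes 2 were called in every fit that left out 1 array, and 11 of 13 lists were. Across genes, the changes with the constructs correlated at r = 0.753 (0.501 for unchanged groups simulated with the pooled spread, 0.378 with that of these groups' own replicates), with a covariance of 0.106 (0.0249 and 0.0162 simulated). They shared 147 genes called higher and 125 called lower, where independent lists would share 3.89 and 3.82, and 2 genes were called in opposite directions. The 2 vector arrays were not split between the comparisons, so part of this excess may come from them.

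The direct comparison of LIN28A-K135R-siR with LIN28A-siR asked what the substitution changes. It called 40 genes, 34 higher and 6 lower with the substitution. COL3A1 was at least 9.53-fold higher (adjusted p = 5.61e-05), THBD 5.56-fold (2.48 ± 0.13), PRRX1 at least 5.06-fold, EDNRA at least 3.85-fold, PDGFRB 2.55-fold (1.35 ± 0.15, adjusted p = 0.00531) and TGFB2 2.33-fold (1.22 ± 0.12, adjusted p = 0.00257). SYT8 was at least 6.11-fold and the inflammatory caspase CASP4 at least 2.07-fold higher, and the decoy receptor IL1R2 was at least 4.35-fold lower. Of the 34 higher genes, 28 were called lower with LIN28A-siR than with vector, and 7 were called higher with LIN28A-K135R-siR than with vector. Each of these comparisons shares arrays with the direct one, and a low level on the LIN28A-siR arrays favours the overlap of 28, so some overlap would arise without any effect. On both LIN28A-siR arrays, 17 of the 34 were below background.

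Of 28 fibroblast genes 2 rose (7 adjusted over the list alone) and 0 fell with K135R relative to LIN28A-siR (median 0.18, adjusted p = 1.86e-10, adjusted p = 0.253 with an estimated correlation). The other lists called, cell cycle (median −0.06, adjusted p = 2.81e-04), oxidative phosphorylation (−0.05, adjusted p = 0.00663) and pluripotency (−0.05, adjusted p = 0.0238), moved little and lost their calls with an estimated correlation (adjusted p = 0.884, adjusted p = 0.888 and adjusted p = 0.884). Without LIN28A-K135R-siR replicate 2 the cell cycle (adjusted p = 0.0746) and oxidative phosphorylation (adjusted p = 0.416) calls were lost, without LIN28A-siR replicate 2 that of oxidative phosphorylation (adjusted p = 0.0698), and without replicate 1 of LIN28A-K135R-siR or of LIN28A-siR that of pluripotency (adjusted p = 0.221 and adjusted p = 0.366). The count of 40 genes was 54 without LIN28A-K135R-siR replicate 1, 67 without its replicate 2, 40 without LIN28A-siR replicate 1 and 71 without its replicate 2. It was 0 in limma on the 4 arrays alone (512 genes had an unadjusted p under 0.05 with all arrays), 20 with normexp, 25 with the deposited values and 13 with only probes above background on all arrays. Of 11 named genes 9 were called in every fit that left out 1 array.

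To ask whether supplied LIN28A reverses the differences seen with LIN28A siRNA, the genes called on slide 1 were followed on slide 2, with no array in both. The 5244 genes higher in LIN28A-siRNA than in EGFP-siRNA had a median change of −0.10 with LIN28A-siR (adjusted p = 2.79e-10, adjusted p = 0.0596 with an estimated correlation) and of −0.09 with LIN28A-K135R-siR (adjusted p = 9.01e-12, adjusted p = 0.0566 with an estimated correlation). The 4627 lower genes had medians of 0.11 and 0.12 (adjusted p = 1.38e-08 and adjusted p = 1.84e-09), and both calls held with an estimated correlation (adjusted p = 0.0331 for both). All other genes had medians of 0.03 and 0.04. The TUT4-siRNA arrays, with no construct, also moved against vector in these directions. Their medians were −0.05 for the higher and 0.08 for the lower genes (0.03 for all others), values examined after the data were seen. These arrays received no LIN28A siRNA, and their LIN28A level (2.60) was near that with LIN28A-siR (2.73) and above that with vector (1.96). All these comparisons also share the vector arrays. Whether the shift comes from supplied LIN28A or from the vector arrays can therefore not be told from these values. With LIN28A-siR, 256 of the higher genes were called lower and 30 higher, and 231 of the lower genes were called higher and 73 lower. In TUT4-siRNA against vector, with no construct, 293 of the higher genes were called lower and 10 higher. Of the lower genes, 34 were called higher there and 21 lower. Between the constructs the medians were 0.01 in both sets (adjusted p = 0.859 and adjusted p = 0.842). Without LIN28A-K135R-siR replicate 1 the higher genes had a median of 0.039 between the constructs (adjusted p = 0.0191).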

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

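In this part, the test of the level of LIN28A, with its bound, was chosen after the results were seen. The effect against vector differed between LIN28A-K135R-siR and LIN28A-siR in 40 genes, which the direct test of the difference between the constructs brought out. The effect against EGFP-siRNA differed between the SET7/9-labelled and LIN28A-siRNA arrays in 28 genes by the same kind of test.

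The 11 fibroblast genes called lower with LIN28A-siR than with vector stood between these groups with K135R, which chance favours since they were chosen for a low level with LIN28A-siR, and the list's call between the constructs (adjusted p = 1.86e-10) was lost with an estimated correlation (adjusted p = 0.253). Whether the level of LIN28A, which differed by −0.11 between the constructs, sets the 11 genes stays undecided: these genes differed between them by a median of 0.55 (0.48 to 0.62 with an array left out), while a bound of 0.5 was set for excluding it. Fibroblast-like cells in the vector cultures, a share of which was lower in the other cultures, stay possible but were not shown. All 6 of the most abundant members in the vector arrays (VIM, LOX, IGFBP7, THY1, COL6A1 and COL1A1) were lower with LIN28A-siR. So were all 28 members tested, so this does not set such cells apart from another cause. The share of the fall that the K135R arrays showed had an interquartile range of 18.7 percentage points over the 11 called genes (54.4% to 73.1%, with extremes of 51.1% for COL3A1 and 84.7% for FN1). Among the 6, VIM (−0.181 against −0.114) and THY1 (−0.385 against −0.325) fell further with K135R than with LIN28A-siR, whereas LOX, IGFBP7, COL6A1 and COL1A1 fell less. Of these 6 only COL1A1 passed the test, VIM differed by −0.11, VIM (0.14) and LOX (−0.08) were close to vector in the TUT4-siRNA arrays, 25 of the 28 members were above background on all 14 arrays, and per the labels cells grown on mouse fibroblast feeders were replated without them. In the direct comparison of the constructs, 2 fibroblast genes passed the test, both among the 11. These were COL3A1 (adjusted p = 5.61e-05, below background with LIN28A-siR) and PDGFRB (1.35 higher with K135R, adjusted p = 0.00531). Whether the substitution itself accounts for these differences stays open. In the TUT4-siRNA arrays, which received neither a LIN28A construct nor LIN28A siRNA, 14 of the 28 fibroblast genes were also called lower than with vector (26 adjusted over the list alone).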

How the results depend on the processing

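The fits of both constructs with TUT4-siRNA as control, of vector against TUT4-siRNA in place of LIN28A-siRNA against EGFP-siRNA, and the correlation without genes above background on no LIN28A-siRNA or SET7/9-siRNA array were chosen after the data were seen. Over 339 settings of the main results 269 kept direction and side of the threshold or stayed within 1.5 times the count, 17 no longer passed, 2 newly passed, 50 moved and 1 reversed. For named genes, 8848 of 9525 settings gave the same call, 560 lost it, 110 gained it and 7 reversed, and for gene lists 1392 of 1606 did, 150 lost it, 57 gained it and 7 reversed. The cause was not tested unless given. No scaling moved the median of all genes by more than 0.1. Signal over background limits the folds of genes near background to lower bounds, and the share of spots well above it was 56.9% to 70.7%.

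Counts for K135R against LIN28A-siR (40) were 20 with normexp, 13 with only probes above background, 0 for 4 arrays, 25 with the deposited values and 40 to 71 with an array left out. For K135R against vector (334) they were 582 with trend and robust, 162 without a filter, 528 with only probes above background, 2 for 4 arrays, 3816 for the slide, 73 with the deposited values, 25 with TUT4-siRNA as control and 5 to 92 with an array left out. For LIN28A-siR against vector (809) they were 1214, 1545 without a filter, 3709 for 4 arrays, 4564 for the slide, 494 with the deposited values, 47 with TUT4-siRNA as control and 96 to 211. For LIN28A-siRNA (9871) they were 5800 for 4 arrays, 6437 for the slide, 442 for vector against TUT4-siRNA and 8588 to 9725, and for SET7/9-siRNA (10117) 6069, 6727 and 8787 to 9912. For SET7/9-siRNA against LIN28A-siRNA (28) they were 10 without a filter, 0 with only probes above background, 2 for 4 arrays, 3 for the slide, 75 with quantile normalization, 63 with the deposited values and 40 to 200, and 71.0% were higher with normexp and 42.9% with the deposited values against 28.6%. For TUT4-siRNA (11181) they were 442 with the vector group as control, 6209 bridged and 9111 to 10971, and for vector against LIN28A-siRNA 10253 to 11524. Fits of fewer arrays have fewer residual degrees of freedom and their own estimate of the spread. Replicates differed by a median of 0.173 to 0.235 on slide 1 and of 0.068 to 0.089 on slide 2. A spread pooled over all arrays lies between these, so counts of the single fit may be too high for slide 1 and too low for slide 2. Over the 8 comparisons camera called 82 lists, and 2 with an estimated correlation.

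LIN28A with K135R (0.67) had an adjusted p of 0.0575 without a filter, 0.052 for 4 arrays and 0.0619 with the deposited values (0.61), and changes of 0.64 to 0.70 with an array left out. With LIN28A-siR these were 0.75 to 0.80. LIN28A in LIN28A-siRNA (−0.38) had an adjusted p of 0.212 for 4 arrays, 0.156 for the slide and 0.052 with the deposited values (−0.31), and changes of −0.59 to −0.17. SETD7 changed by 0.072 to 0.80 and TUT4 by 0.80 to 0.93, by 0.045 with vector as control and by −0.33 bridged. The correlation of 0.952 was 0.938 without a filter, 0.968 with only probes above background, 0.939 with quantile normalization and 0.927 to 0.959. Medians of raised genes between the constructs were −0.016 to 0.039.

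Directions reversed for ESPNL with only probes above background, where another of its probes took over (−0.65 in LIN28A-siRNA, −0.72 in SET7/9-siRNA, −0.37 in TUT4-siRNA), for RPS2 in vector against LIN28A-siRNA (0.32 with normexp, 0.37 with quantile normalization, 0.44 with the deposited values) and for SOX17 in SET7/9-siRNA with quantile normalization (−0.18). Bridged, the TUT4-siRNA lists HOX (adjusted p = 0.159), glycolysis (adjusted p = 1.21e-11), p53 (adjusted p = 1.66e-06) and trophoblast (adjusted p = 1.54e-04) reversed. So did germ cell genes in vector against LIN28A-siRNA with fry (adjusted p = 0.00506), and oxidative phosphorylation (adjusted p = 1.6e-05, range with an array left out 3.89e-10 to 0.804) and ribosomal proteins (adjusted p = 0.13, range 6.85e-20 to 0.47) in SET7/9-siRNA against LIN28A-siRNA without LIN28A-siRNA replicate 1.

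With the replicate number as a block, the counts were 9846, 10067, 11104, 760, 279, 41, 20 and 12030, in the order LIN28A-siRNA, SET7/9-siRNA, TUT4-siRNA, LIN28A-siR, K135R, K135R against LIN28A-siR, SET7/9-siRNA against LIN28A-siRNA and vector against LIN28A-siRNA, and 83 lists were called. Over 21 pairs of groups, same-numbered arrays deviated together at correlations of −0.0472 to 0.0918, 0 of them above 0.1. No strong pairing by number is visible in these values, which cannot exclude a shared day or culture.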

Other observations

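In this part, the test of loss of LIN28A for the 307 genes and both tests of a mixture of stocks of cells were chosen after the results were seen. Beyond glycolysis and p53 targets, the vector arrays of slide 2 differed from the LIN28A-siRNA arrays of slide 1 in several further groups of genes, in a comparison that crosses slides. HOX genes were higher with vector in 19 of 27 cases and lower in 1, also adjusted over the list alone (median 1.63, adjusted p = 6.26e-05, adjusted p = 0.319 with an estimated correlation), with HOXC4 at least 22.8-fold and HOXA13 at least 5.48-fold higher. Trophoblast markers were lower in 12 of 19 cases and higher in 1, also over the list alone (median −1.56, adjusted p = 0.0171, adjusted p = 0.319 with an estimated correlation), including the transcription factor GATA3 (11.9-fold) and the chorionic gonadotropin subunit CGB3 (8.59-fold). Interferon response genes were lower in 20 of 27 cases and higher in 5, also over the list alone (adjusted p = 0.0261, adjusted p = 0.533 with an estimated correlation), led by ISG15 (4.78-fold). Genes of the unfolded protein list were lower in 31 of 45 cases and higher in 6 (32 and 6 adjusted over the list alone; adjusted p = 0.00714, adjusted p = 0.533 with an estimated correlation), and heat shock genes in 15 of 22 and higher in 1, also over the list alone (adjusted p = 0.0152, adjusted p = 0.533 with an estimated correlation).

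LIN28B, the paralog of LIN28A, had log2 levels of 4.82 in EGFP-siRNA, 4.32 in LIN28A-siRNA, 4.12 in the SET7/9-labelled arrays, 3.59 in TUT4-siRNA and 3.35 with vector.

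The differences between LIN28A-siRNA and EGFP-siRNA cover most genes tested. Loss of LIN28A as their main cause is argued against by slide 2: there the vector arrays, which also received LIN28A siRNA and whose LIN28A lay 0.64 below that of TUT4-siRNA, followed the same genes with a slope of 0.0899 (0.0737 to 0.106 with an array left out). LIN28A-siR and LIN28A-K135R-siR, set against vector, gave slopes of −0.1 and −0.103, and the reading assumes that TUT4 siRNA does not itself move these genes. The dimmer signal of the LIN28A-siRNA arrays is argued against as the whole cause, since a curve on mean level took 6.09% of the variance of the changes and quantile normalization kept 85.9% of the calls. A difference between the cultures on slide 1 other than the siRNA stays open.

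On slide 1, 307 genes were well above background on all EGFP-siRNA and slide 2 arrays and on none of the 4 LIN28A-siRNA and SET7/9-siRNA arrays. CTAG1A, for example, stood at 5.19 and 4.10 in EGFP-siRNA, −6.32 on average in those 4 arrays and 6.09 on slide 2, and OLIG3 at 1.42, 0.45, −4.70 and 2.81. Loss of LIN28A is argued against for this set: in the 371 genes found with the TUT4-siRNA arrays in place of all slide 2 arrays, and so chosen without the vector arrays, vector and TUT4-siRNA differed by a median of −0.12 (−0.13 to −0.09), and 4 were below background on both vector arrays. A mixture of 2 stocks of cells on the EGFP-siRNA arrays, in unequal shares, stays open: replicate 2 lay below replicate 1 in the 307 genes by a median of −0.54 (interquartile range 0.805, against a median of 0.06 and an interquartile range of 0.456 over all genes), in the 79 with a slide 2 mean above −2 by −0.99 (0.381), and 54 genes with the opposite pattern went the other way (median 0.50, interquartile range 0.734), so the amount was not shown to be constant. Whether these genes stand at their slide 2 level in 1 of the stocks cannot be told apart from other mixtures, since the distance to that level varied over the 79 genes (interquartile range 0.876), and no other biological explanation was tested.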
